A study of Flaveria angustifolia and Flaveria bidentis and Flaveria brownii with 21 samples.

How the data were processed

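Leaf RNA was sequenced from species of Flaveria, a genus of the daisy family whose species range from C3 through intermediate to C4 photosynthesis. The series holds 21 samples. Of these, 18 are Flaveria libraries from 11 species and 3 are out-group species of the same plant family, which were not analysed here. Juvenile leaves, which had just begun to expand, gave 10 Flaveria libraries. The newest fully expanded leaf, called mature here, gave 8. Each library pooled leaves of several greenhouse plants, and each species and stage had 1 library. RNA was extracted with hot acid phenol, purified on columns with DNase treatment and sequenced on the Illumina platform, per the labels' protocols.

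The authors deposited 1 table of RPM, reads scaled to a total of 1e+06 per library, with 20551 Arabidopsis loci and 1 column for each of the 18 Flaveria libraries. The loci comprised 20431 nuclear, 74 chloroplast and 46 mitochondrial loci. Arabidopsis genome build TAIR10 was named, per the submitters' processing notes. The aligner or assembler, the counting rule and the treatment of reads that match several loci were not given in the sources used here. Values of a locus therefore describe the Flaveria reads assigned to that Arabidopsis locus, and members of a gene family are reported as uncertain because such reads could have been split between them. Every column of the deposited RPM table summed to 1e+06, and 100% of the values were whole multiples of the value of 1 read (tolerance 0.001 of a read). The read totals recovered this way ran from 5.40 to 9.15 M (M, 1e+06 reads) per library. At these totals a value of 0, taken as fewer than 3 reads, allows up to 0.328 RPM in the deepest library and 0.556 RPM in the shallowest. These limits cover counting error only.

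Libraries were grouped by species and leaf stage as the labels give them. The photosynthetic type of each species is textbook knowledge and not a label. F. cronquistii and F. pringlei were taken as C3. F. angustifolia, F. pubescens and F. sonorensis were taken as C3-C4 intermediates. F. brownii, F. palmeri and F. vaginata were taken as C4-like, and F. bidentis, F. kochiana and F. trinervia as C4. P-values do not measure the spread between plants of a species. In the stage fits and the permutation tests the species was the replicate. In the type fits the stages of a species entered as separate libraries, with a single correlation shared by all loci. Those p-values therefore rest partly on libraries. With 1 value per species the loci that passed went from 184 to 1 for C4 against C3. They went from 29 to 0 for C4-like against C3, and from 203 to 6 for the C4 and C4-like species against the others.

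Tests ran on log2(RPM + 1) with limma 3.58.1 in R 4.3.3, using moderated variances with a mean trend, for loci with a mean of at least 2 RPM in the libraries of the fit. Fold changes are on the log2(RPM + 1) scale, which understates changes of low loci. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. They were two-sided, except in the permutation tests of library similarity, which were one-sided and not adjusted. Mature leaves were compared with juvenile leaves in the 14 libraries of the 7 species that had both stages, with species as a block. The pairing comes from the species named in the labels. It was checked on Spearman correlations over loci, whose mean was 0.842 between the stages of a species and 0.758 between different stages of different species (exact permutation p = 0.000198, the smallest that the pairings of 7 species can give). That check concerns the mean, and 5 of the 7 juvenile libraries were closest to the mature library of their own species. Types were compared in all 18 libraries with stage as a covariate and species as a random block, whose estimated correlation (limma with statmod 1.5.0) was 0.493. In the type comparisons, RPM values of a species or type average the stages that each species had, without centring for stage. The last type comparison set the mean of the C4 and C4-like coefficients against the mean of the C3 and C3-C4 coefficients. Whether the stage difference itself differed by type was tested on the mature minus juvenile differences of the 7 paired species. Comparisons of library similarity used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

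Before the data were examined, 23 gene lists were fixed by Arabidopsis locus, with 358 loci, of which 356 were in the table. They cover the C4 cycle, photosynthesis, carbon and nitrogen metabolism, growth, stress, and markers of other tissues. Symbols are given only for loci of these lists. The files do not pair loci with names, and other loci keep their identifiers. Lists were tested with camera at a preset inter-gene correlation of 0.01, with p-values adjusted over the 23 lists of a comparison, and again with an estimated correlation and with fry. Named genes followed a rule fixed at the same time. It took up to 4 members per list with the largest change among those past the threshold, or the 2 members with the smallest p where none passed. It also took the 10 highest and 10 lowest changes among loci with a mean of at least 10 RPM that moved in the same direction in every pair or did not overlap between the types. The C4 cycle enzymes with a mean of at least 50 RPM were added in every type comparison. A few values of other list members are given as well and are named as chosen after their values were seen.

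Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 RPM, no filter and a filter of 10 RPM, scaling by TMM factors and by quantiles, a fit without the trend, leaving out each species, other treatments of the species term, and separate stages. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood with TMM) and limma-voom on the recovered reads, thinning of all libraries to 5399898 reads, sums over gene families tested by exact permutation over species, fits without the mature F. brownii library, and camera with that library or each species left out (species correlation as in the full fit). The edgeR fit of the types had no species term and so treats the stages of a species as independent.

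The fits were tested on simulated reads in which 200 loci were changed. The changed loci had a mean of at least 10 RPM. Every locus was given the same spread between species and between libraries, and loci varied independently. Real loci differ in spread, so the shares below describe the simulation and need not hold for the real fits. In the stage fit of 14447 simulated loci, 92% of the loci changed 2-fold and 100% of those changed 4-fold were recovered. In the fit of C4 against C3 with 14436 simulated loci, 4% of the loci changed 2-fold, 68% of those changed 4-fold and 96% of those changed 8-fold were recovered. In the fit of C4 and C4-like against the other species, with 14442 simulated loci, 32% at 2-fold and 100% at 4-fold were recovered. Unchanged loci made up 3.45%, 8.22% and 4.60% of the calls in these 3 simulations.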

Results

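The 18 Flaveria libraries held 6.68 ± 1.11 M assigned reads (M, 1e+06 reads; mean ± SD, n = 18), with 6.53 ± 1.07 M in the 10 juvenile and 6.86 ± 1.21 M in the 8 mature libraries. The C4 libraries were deeper (7.97 ± 0.968 M, n = 5) than the C3 (5.71 ± 0.441 M, n = 4), C3-C4 (6.54 ± 0.796 M, n = 5) and C4-like libraries (6.21 ± 0.632 M, n = 4). The 50 most abundant loci took 27.0 ± 3.36% of the reads of juvenile libraries and 34.1 ± 4.82% of those of mature libraries. The series was collected to reconstruct the relationships within the genus, and its design sets species of different photosynthetic type and leaves of different age side by side.

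Leaf age was compared first. In mature leaves all 31 tested genes of the cell cycle and DNA replication list, all 24 of the cytosolic ribosome list and 16 of 21 leaf development and vein regulators were lower than in juvenile leaves of the same species. Of 16 photosystem I genes and of 24 C4 cycle enzymes 11 each were higher, and of 9 senescence genes 6. Camera called each of these 6 lists, and none of the calls held with an estimated correlation (adjusted p from 0.321 to 0.436). AUR1, which encodes a mitotic Aurora kinase, went from 21.2 ± 8.05 RPM in juvenile leaves to 0.442 ± 0.291 RPM in mature leaves (mean ± SD, n = 7 species). PPDK, which regenerates the acceptor of the C4 cycle, rose by 1.49 ± 0.32 (log2 fold change ± SE), and it was higher in mature leaves of 7 of the 7 species.

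In limma, 7291 of 14500 tested loci differed at an adjusted p under 0.05, with 1843 higher and 5448 lower in mature leaves. The median over all loci was −0.31 on the log2 scale. With TMM scaling that median was near 0 (−0.0013) and 6543 loci passed, 3355 higher and 3188 lower, of which 5031 also passed without TMM. Of the loci that passed, 25.3% were higher as deposited and 51.3% with TMM. List medians are therefore also given relative to the median of all loci. Below, camera p-values are adjusted over the lists, and none of the 14 lists that camera called held with an estimated correlation.

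The cell cycle list had a median of −2.76, or −2.45 relative to all loci (camera adjusted p = 3.1e-14; adjusted p = 0.321 with an estimated correlation). Besides AUR1 (−3.83 ± 0.28), TOPII, a DNA topoisomerase, fell by 3.72, and MCM4 and MCM2, subunits of the replicative helicase, fell by 3.65 and 3.64. All 31 also passed when adjusted over the list alone, and 30 with TMM. All 24 tested cytosolic ribosome genes fell as well, with a median of −1.65 (adjusted p = 9.0e-10; adjusted p = 0.345 with an estimated correlation), and all 24 passed adjusted over the list alone. RPL23aA, a large subunit protein, fell by 1.98 and RPL24A by 1.93.

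Of 21 leaf development and vein regulators, 16 fell and 1 rose, and equal numbers passed adjusted over the list alone. With TMM 13 fell and 2 rose. The 1 that rose, GLK2, a regulator of chloroplast development, was at 0.57 and was named after its value was seen. Their median was −1.30 (camera adjusted p = 0.0017; adjusted p = 0.436 with an estimated correlation). GRF5 and its partner AN3, which promote cell proliferation in leaves, fell by 2.61 and 2.01. MP, an auxin response factor needed for vein formation, fell by 2.40, and ANT, a growth regulator of young organs, by 2.24. Among 7 epidermis, stomata and trichome markers, 6 fell, and 6 adjusted over the list alone (camera adjusted p = 0.0061; adjusted p = 0.321 with an estimated correlation). The stomatal patterning receptor TMM had a change of −4.08 ± 0.33, and SDD1, a protease of stomatal patterning, one of −2.40.

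In the secondary cell wall and xylem list 14 of 20 members fell, 14 adjusted over the list alone, with a median of −0.91 (camera adjusted p = 0.0448; adjusted p = 0.556 with an estimated correlation). With TMM 11 fell and 2 rose. The list call ended without F. angustifolia (camera adjusted p = 0.0528), F. pubescens (0.0505), F. brownii (0.0666), F. bidentis (0.0599) or F. trinervia (0.0739). PAL1 and C4H, which open the phenylpropanoid pathway, fell by 2.64 and 2.33, and the laccase LAC17 by 2.48. Of 8 primary cell wall genes 6 fell, 6 adjusted over the list alone, led by the expansin EXPA4 at −2.19, while camera did not call the list (adjusted p = 0.212). With TMM, 3 of these 8 were lower and 1 higher. Chlorophyll synthesis genes fell in 10 of 17 cases, 10 adjusted over the list alone, but with TMM 6 were lower and 3 higher (camera adjusted p = 0.0448; adjusted p = 0.565 with an estimated correlation). TMM scaling also ended this list call (camera adjusted p = 0.0877), as did leaving out F. cronquistii (0.0973), F. angustifolia (0.0545) or F. brownii (0.101). GSA1 and GSA2, which make the precursor aminolevulinate, fell by 1.93 and 1.91, and CHLD, a subunit of magnesium chelatase, by 1.49.

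Photosystem I genes rose in 11 of 16 cases, 13 adjusted over the list alone and 15 with TMM, with a median of 0.47 (0.78 relative to all loci; camera adjusted p = 1.1e-06; adjusted p = 0.321 with an estimated correlation). In F. brownii this list median was −0.0022, against 0.38 to 0.78 in the other 6 species. PSAG rose by 0.97 ± 0.18 and LHCA3, an antenna protein, by 0.80 ± 0.17. In the photosystem II list 5 of 24 rose, 2 adjusted over the list alone and 19 with TMM (camera adjusted p = 3.1e-06; adjusted p = 0.436 with an estimated correlation). The list median was −0.60 in F. brownii and 0.35 to 0.74 in the other 6 species, and without F. brownii 18 rose. PSBY rose by 0.96, PSBR by 0.84, LHCB3 by 0.54 and PSBX by 0.53, and PSBW, named after its value was seen, by 0.47. The cyclic electron flow list had 10 of 20 higher and 1 lower, 11 and 2 adjusted over the list alone (camera adjusted p = 4.0e-05; adjusted p = 0.321 with an estimated correlation). NDHT, part of the chloroplast NDH complex, rose by 1.98 ± 0.28, and PGRL1B, of the other cyclic route, by 1.41. PNSL5 fell by 1.18.

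Of the 24 C4 cycle enzymes, 11 rose and 1 fell, 12 and 1 adjusted over the list alone, and 16 rose with none lower under TMM (median 0.47; camera adjusted p = 8.0e-07; adjusted p = 0.321 with an estimated correlation). The list median was 1.41 in F. pubescens and 0.21 to 0.58 in the other 6 species. Without F. pubescens 10 rose and 1 fell (median 0.36, camera adjusted p = 4.0e-05). PPCK2 and PPCK1, kinases of PEP carboxylase, rose by 1.81 and 1.52, and RP1, which regulates PPDK, by 1.38. The 1 that fell, PPA6, a pyrophosphatase named after its value was seen, was at −0.69 with an adjusted p of 0.0128. An exact sign-flip test over the 7 species, whose smallest p is 0.0156, put 8 of the 24 at an adjusted p of 0.0469 over the list alone. All 8 stood at that smallest p, so the adjusted p depends on how many loci share it. They include PPC1, PPC2 and PPC3, loci of PEP carboxylase that cannot be separated here. Of 7 C4 metabolite transporters PPT2 and NHD1 rose by 0.99 and 0.75 and DiT1 fell by 0.81, a call that TMM scaling ended (−0.46, adjusted p = 0.110). The same 3 passed adjusted over the list alone, and 3 rose with TMM (median −0.03, mean 0.13). The list was not called (camera adjusted p = 0.161). Other decarboxylases had 2 of 3 lower, 2 adjusted over the list alone, with PCK1 at −1.21 and NAD-ME1 at −0.70 (camera adjusted p = 0.334). With TMM only PCK1 passed, and NAD-ME1 was at −0.35 (adjusted p = 0.0882).

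In the photorespiration list 8 of 24 genes rose and 6 fell, whereas with TMM 11 rose and none fell (median −0.09, mean 0.19; camera direction up, adjusted p = 0.0114; adjusted p = 0.556 with an estimated correlation). Leaving out F. pubescens ended the list call (camera adjusted p = 0.0582). CAT2, the catalase of leaf peroxisomes, went from 2171 ± 796 to 6815 ± 4053 RPM, and GOX1 and GGT2, also of the peroxisome, rose by 1.27 and 1.21. The Calvin-Benson cycle had 9 of 22 higher and 2 lower, and 10 higher and 0 lower with TMM (median −0.01, mean 0.23; camera direction up, adjusted p = 0.0031; adjusted p = 0.556 with an estimated correlation). The list median was 0.93 in F. pubescens and −0.09 to 0.18 in the other 6 species. Without F. pubescens 8 were higher and 2 lower (median −0.15, camera direction up, adjusted p = 0.0443). FBA1, a chloroplast aldolase, rose by 1.02. RBCS3B, a Rubisco small subunit, and RPI3, an isomerase, were the 2 lower, at −0.51 and −0.39, and were named after their values were seen. In both lists equal numbers passed adjusted over the list alone.

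Senescence genes rose in 6 of 9 cases, 7 adjusted over the list alone (median 0.96; camera adjusted p = 6.9e-05; adjusted p = 0.321 with an estimated correlation). The list median differed between species, at 2.35 in F. brownii, 1.67 in F. cronquistii, 0.02 in F. pubescens and 0.28 to 0.71 in the other 4. Without F. brownii, whose mature library also had the highest mitochondrial share of the mature libraries, 5 of 8 rose and SAG13 fell (median 0.75, camera adjusted p = 5.8e-04), and without F. cronquistii 5 of 9 rose (median 0.96, camera adjusted p = 8.8e-05). SAG12, a cysteine protease of ageing leaves, rose by 2.89 ± 0.57 and was higher in 6 of 7 species. It stood at 160.7 ± 314.5 RPM in mature leaves (SD, n = 7 species), with 865.0 RPM in F. brownii, and without that species its change was 2.40 (adjusted p = 0.00363). SEN1 rose by 1.82. Of 5 phloem companion cell markers 3 rose and 1 fell, 3 and 1 adjusted over the list alone (camera adjusted p = 0.0345; adjusted p = 0.321 with an estimated correlation), a list call that TMM scaling (camera adjusted p = 0.0671) and leaving out F. pubescens (0.0534) ended. The sucrose carriers SUC2 and SWEET12 rose by 1.41 and 1.08, the proton pump AHA3 rose by 0.71, and the transcription factor APL fell by 0.98.

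The remaining lists were not called. In starch and sucrose 5 of 22 were higher and 5 lower, and equal numbers passed adjusted over the list alone, while with TMM 6 were higher and 1 lower (median −0.29; camera direction up, adjusted p = 0.280). The starch and sucrose median was 0.78 in F. pubescens and −0.52 to −0.03 in the other 6 species, and without F. pubescens 5 were higher and 9 lower. SPSC, a sucrose-phosphate synthase, rose by 2.24, the amylases BAM1 and BAM3 rose by 1.35 and 1.07, and DPE1, of starch breakdown, fell by 1.62. Nitrogen assimilation had 2 of 8 higher and 3 lower, equal numbers adjusted over the list alone, and 4 and 2 with TMM (camera adjusted p = 0.290). The nitrate reductases NIA2 and NIA1 rose by 1.44 and 1.35, and GDH1, a glutamate dehydrogenase, fell by 0.86. In jasmonate and defence PR2, a glucanase, rose by 3.08 and LOX2, of jasmonate synthesis, fell by 1.23, a call that TMM scaling ended (−0.88, adjusted p = 0.105). These 2 of 6 also passed adjusted over the list alone (median −0.14, mean 0.41; camera adjusted p = 0.308). The circadian clock list had 2 of 9 lower, PRR7 at −0.74 and ELF3 at −0.62, 2 adjusted over the list alone, but 1 higher and 0 lower with TMM (median 0.07, mean −0.04; camera adjusted p = 0.387). Of 3 shoot meristem and flower markers SEP3 was lower at −0.98, 1 adjusted over the list alone and 0 with TMM, where it was at −0.74 (adjusted p = 0.0546; camera adjusted p = 0.775). Of 8 heat shock genes 0 passed in limma, 0 adjusted over the list alone and 2, both higher, with TMM (median −0.03; camera direction up, adjusted p = 0.334). HSP17.4 was at 0.30 (adjusted p = 0.195).

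Outside the lists, AT2G34080 rose by 4.61 ± 0.57 and AT3G49340 by 3.94 ± 0.64, each in 7 of 7 species. AT3G04290 went from 987.8 ± 490.9 to 9.39 ± 5.36 RPM and AT5G33370 from 803.3 ± 286.5 to 9.85 ± 6.29 RPM. Without the species block 3840 loci passed, and with edgeR on the recovered reads 6341 (3279 higher, 3062 lower). The mitochondrial share of reads was 0.484 ± 0.211% in juvenile and 0.224 ± 0.179% in mature libraries.

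**Figure D1:**
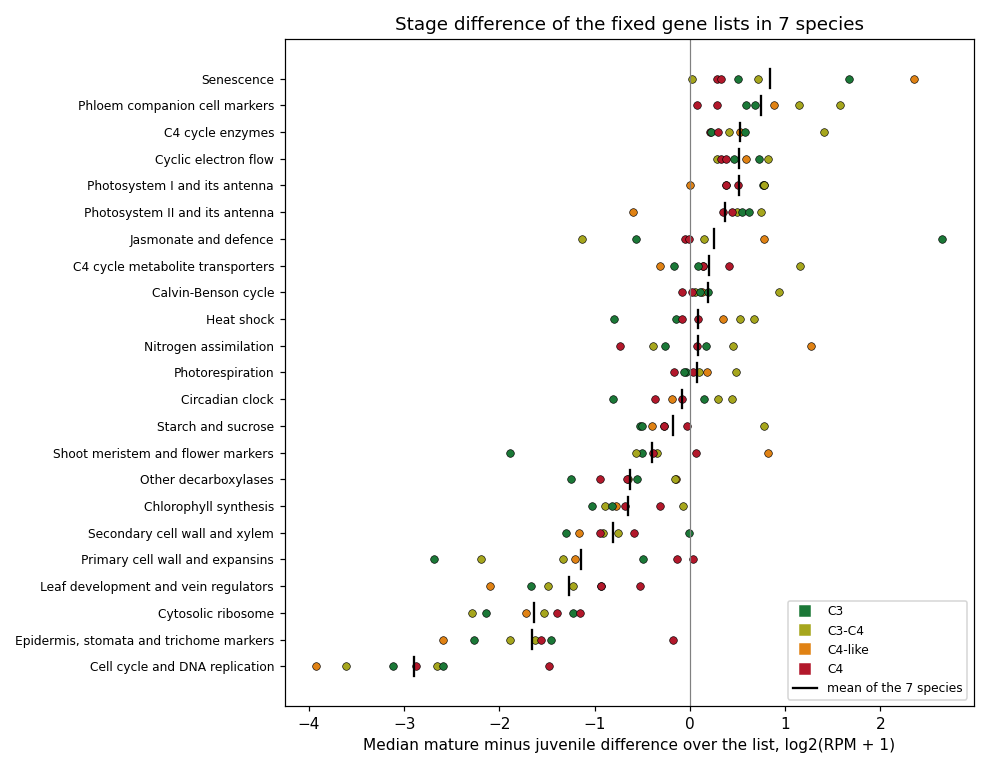
Median difference in log2(RPM + 1) between mature and juvenile leaves for each of the 23 gene lists, with a point per species (7 species) and a bar at the mean of the species. The C4 cycle median of F. pubescens was 1.41 and the photosystem II median of F. brownii was −0.60.

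The photosynthetic types were compared next, beginning with C4 against C3. C4 species had far more transcript for the enzymes and transporters of the C4 cycle and more for cyclic electron flow, and less of 3 photorespiratory genes. PPDK averaged 26311 ± 10859 RPM in the 3 C4 species and 295.7 ± 224.6 RPM in the 2 C3 species (mean ± SD of species), a log2 fold change of 6.68 ± 0.88 (SE). PPC1, a PEP carboxylase and so the first enzyme of the cycle, rose from 627.2 ± 93.7 to 18994 ± 3157 RPM. Of the 24 C4 cycle enzymes 17 were higher and none lower. By textbook knowledge the 3 C4 species belong to a single lineage, clade A. Photosynthetic type and shared ancestry therefore cannot be told apart in this comparison.

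In limma, 184 of 14479 loci passed, 116 higher and 68 lower in C4, and 174 with TMM. TMM moved the median of all loci from −0.12 to −0.01. The C4 enzymes had a median of 3.90, or 4.02 relative to all loci, and 20 passed adjusted over the list alone (camera adjusted p = 2.1e-38; adjusted p = 0.0032 with an estimated correlation). NADP-ME1, a malic enzyme that releases CO2, was higher by 5.10 ± 0.73, NADP-MDH, which makes malate, by 3.95, and the aminotransferases AlaAT1 and ASP5 by 4.02 and 3.93. AMK2 and PPA6, an adenylate kinase and a pyrophosphatase that clear the products of PPDK, were higher by 4.95 and 2.35. The 4 carbonic anhydrases CA1 to CA4 did not pass, with CA1 at 0.43 ± 0.52. Paralogs of PEP carboxylase moved almost together over the 18 libraries (Pearson r from 0.992 to 0.999 between its 3 loci), so the loci of such a family cannot be separated here. For NADP-malic enzyme r was 0.908 to 0.981 and for alanine aminotransferase 0.996. The range was wide for aspartate aminotransferase (0.015 to 0.952) and carbonic anhydrase (0.223 to 0.911). Counts of C4 enzymes may therefore count the same reads more than once, and camera at its preset correlation takes such loci as nearly independent.

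Of the 7 transporters 5 were higher, 4 with TMM, and 7 adjusted over the list alone (camera adjusted p = 6.2e-15; adjusted p = 0.0168 with an estimated correlation). NHD1 and BASS2, which together move sodium and pyruvate across the chloroplast envelope, were higher by 4.80 ± 0.51 and 4.42 ± 0.49. PPT1, a carrier of PEP, was higher by 3.15, DiT2.2 by 2.69 and DiT1, named after its value was seen, by 1.98. DiT1 did not pass with TMM (adjusted p = 0.0589), although its change was no smaller there. Of 20 cyclic electron flow genes 12 were higher, and 19 adjusted over the list alone (camera adjusted p = 1.4e-28; adjusted p = 0.0113 with an estimated correlation). The NDH subunits PNSL1, NDHL and NDHO were higher by 2.67, 2.58 and 2.42.

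In photorespiration 3 of 24 were lower, and 13 lower and 2 higher adjusted over the list alone (camera adjusted p = 5.0e-09; adjusted p = 0.144 with an estimated correlation). They were mLPD1 and mLPD2, subunits of glycine decarboxylase and other dehydrogenases, at −2.44 and −2.25, and GS2, the chloroplast glutamine synthetase, at −2.15. The Calvin-Benson list was not called (camera adjusted p = 0.176). In it RBCS1A (−2.63), RCA (−2.25) and CP12-2 (2.47) passed, and 2 were higher and 6 lower adjusted over the list alone. With TMM none of the 3 passed, at changes of −2.51, −2.13 and 2.59 (adjusted p = 0.0775, 0.0939 and 0.0535). Photosystem I had 2 of 16 higher, PSAN at 1.84 and PSAD2 at 1.80, and 6 adjusted over the list alone (camera adjusted p = 1.7e-09; adjusted p = 0.232 with an estimated correlation), of which PSAD2 alone passed with TMM, while PSAN was at 1.96 (adjusted p = 0.0618). Camera also called heat shock (adjusted p = 0.0067; adjusted p = 0.381 with an estimated correlation) and starch and sucrose (adjusted p = 5.3e-04; adjusted p = 0.437 with an estimated correlation) as higher, with no member past the threshold in limma. Leaving out F. kochiana ended the heat shock call (camera adjusted p = 0.0747). SCR, a regulator of endodermis and bundle sheath identity, was higher by 3.16 and SWEET12 lower by a log2 change of −1.89. Outside the lists AT1G76560 rose by 6.54 and AT3G56160 by 4.56, while AT4G16980 was at −8.07 and AT2G07599 at −6.70. The C4 mean of AT4G16980 was 0.225 RPM, below the limit that a count of 0 allows in each library, so its fold change depends on the pseudocount.

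Leaving out F. cronquistii or F. pringlei leaves 1 C3 species, which is then assumed to vary like the other groups. Leaving out F. cronquistii, F. bidentis or F. trinervia gave 38, 71 or 78 loci, of which 25, 68 and 75 were among the 184. Without F. pringlei 145 passed, 87 of them among the 184. With 1 value per species 1 locus passed, with juvenile libraries alone 12, with mature libraries alone 29, with limma-voom 105, and with edgeR without a species term 1123.

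**Figure D2:**
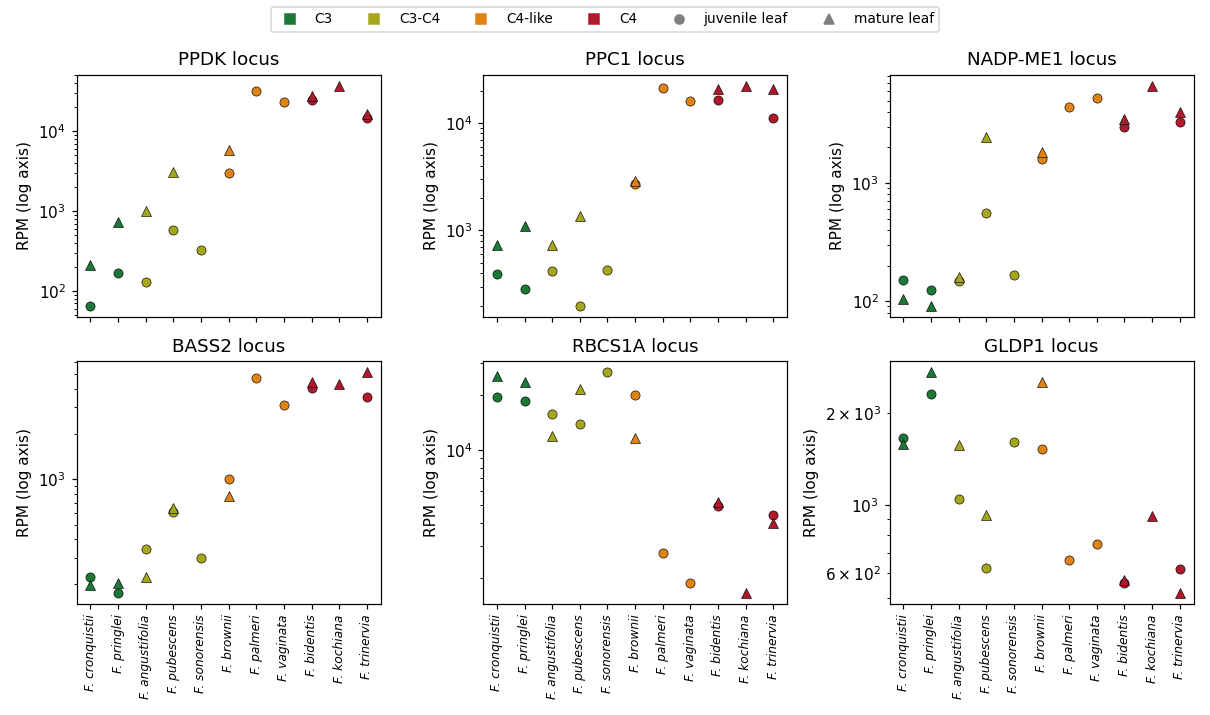
RPM on a log axis of PPDK, PPC1, NADP-ME1, BASS2, RBCS1A and GLDP1 in each of the 18 libraries, by species, with colour for the type and circles for juvenile and triangles for mature leaves. PPDK averaged 295.7 RPM in the C3 species and 26311 RPM in the C4 species.

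The C4-like species were then compared with the C3 species, and C4 cycle transcripts were again much higher. PPDK was higher by 6.37 ± 0.91, NADP-ME1 by 4.87 ± 0.75, PPC1 by 4.25 ± 0.74 and RP1 by 4.58 ± 0.66. F. brownii had 4370 RPM of PPDK, F. palmeri 32243 RPM and F. vaginata 23479 RPM. The value of F. brownii averages both stages and the others are from juvenile leaves alone, so leaf age enters them. In limma 29 loci passed, 22 higher and 7 lower, and 14 of the 24 C4 enzymes were among the higher (20 adjusted over the list alone; camera adjusted p = 5.1e-46; adjusted p = 0.00135 with an estimated correlation). Of the 7 transporters 3 were higher, NHD1 by 3.92, BASS2 by 3.37 and PPT1 by 2.58, and 6 adjusted over the list alone (camera adjusted p = 9.7e-14; adjusted p = 0.0323 with an estimated correlation). With TMM 26 loci passed, 25 of them among the 29. The C4 enzyme NADP-ME3 was at 3.21 with TMM and only its adjusted p crossed the threshold (0.0411 as deposited, 0.0788 with TMM). The change of PPT1 was 2.54 with TMM, and its adjusted p crossed as well (0.0454 as deposited, 0.120 with TMM). In cyclic electron flow 1 of 20 passed, PNSB5 at 1.59, and 13 adjusted over the list alone (camera adjusted p = 2.4e-19; adjusted p = 0.0323 with an estimated correlation). With TMM the change of PNSB5 was 1.54 and its adjusted p 0.100 (0.0232 as deposited). SWEET12 had a change of −2.15.

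Camera called 4 lists as lower in the C4-like species, with no member past the threshold in limma. The Calvin-Benson cycle had 3 lower adjusted over the list alone and photosystem II 1. The lists were photosystem II (adjusted p = 6.9e-07; adjusted p = 0.474 with an estimated correlation), photorespiration (adjusted p = 1.9e-08; adjusted p = 0.167 with an estimated correlation), the Calvin-Benson cycle (adjusted p = 0.0048; adjusted p = 0.535 with an estimated correlation) and the epidermis markers (adjusted p = 0.0312; adjusted p = 0.474 with an estimated correlation), the last not with TMM (adjusted p = 0.0546). The only mature C4-like library was that of F. brownii, whose mitochondrial share was 0.640% against 0.0494 to 0.241% in the other mature libraries and whose photosystem II stage median was −0.60 against 0.35 to 0.74 in the other 6 species. Without this library the photosystem II list median went from −0.34 to −0.19 and camera still called it (adjusted p = 0.0281), and the Calvin-Benson call ended (adjusted p = 0.0626). Without both libraries of F. brownii neither was called (adjusted p = 0.0870 for photosystem II, median −0.27, and 0.128 for the Calvin-Benson cycle). Leaving out F. pringlei ended the calls of the Calvin-Benson cycle (adjusted p = 0.128) and the epidermis markers (adjusted p = 0.136). The count of 29 was 46 with no filter, 60 with edgeR, 19 with limma-voom and 0 with 1 value per species or in juvenile libraries alone. Without F. cronquistii 3 loci passed, 0 higher and 3 lower, and 0 of the 29 were among them. That fit holds 1 C3 species, assumed to vary like the other groups, and the changes stayed large in it, with PPDK at 5.56 (adjusted p = 0.121), NADP-ME1 at 5.02 (0.102) and PPC1 at 4.21 (0.224). Without F. pringlei 24 passed, 9 of them among the 29. Leaving out F. brownii gave 79 loci (27 of the 29), F. palmeri 12 (12 of the 29) and F. vaginata 15 (13 of the 29).

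The C3-C4 species were compared with the C3 species, and no locus passed in limma. ASP1, an aspartate aminotransferase, had the smallest p among C4 enzymes, with 232.5 ± 7.90 against 68.4 ± 4.40 RPM (log2 difference 1.75 ± 0.38, adjusted p = 0.295). PPDK differed by 1.66 ± 0.88 and PPC1 by 0.01 ± 0.72. GLDP1 and GLDP2, the P protein of glycine decarboxylase, were at −0.79 ± 0.42 and −1.05 ± 0.41 (adjusted p = 0.970 and 0.921). In limma 0 loci passed and 744 had an unadjusted p under 0.05, where 724 would by chance. edgeR passed 14 loci, limma-voom 0, limma without a filter 10 and mature libraries alone 2. Leaving out F. pringlei, F. cronquistii, F. pubescens or F. sonorensis gave 19, 5, 3 or 2 loci, with 1 C3 species left in the first pair of fits. Camera called the C4 enzymes as higher (median 1.04, adjusted p = 9.8e-09; adjusted p = 0.599 with an estimated correlation), 1 of them adjusted over the list alone, and photosystem I (adjusted p = 0.0063; adjusted p = 0.993 with an estimated correlation), the latter not without F. cronquistii (adjusted p = 0.756). Among the C3-C4 species NADP-ME1 was at 1511 RPM in F. pubescens, 154.4 RPM in F. angustifolia and 166.8 RPM in F. sonorensis. The value of F. sonorensis is from juvenile leaves alone and the others average both stages, so leaf age enters them.

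The C4 species were compared with the C4-like species, and again no locus passed in limma. The photosystem I subunits PSAN and PSAE2 were at 1.70 ± 0.40 and 1.72 ± 0.48 (adjusted p = 0.326 and 0.523). PPDK differed by 0.31 ± 0.85. In limma 0 loci passed and 1133 had an unadjusted p under 0.05. edgeR passed 14 loci, limma-voom 0 and limma without a filter 1. Leaving out F. kochiana, F. vaginata, F. palmeri or F. pringlei gave 5, 4, 1 or 1 loci. TMM moved the median of all loci from −0.16 to −0.02. Camera called 9 lists, led by photosystem I (median 0.91, adjusted p = 2.2e-14), photosystem II (0.50, adjusted p = 3.5e-11) and cyclic electron flow (0.53, adjusted p = 4.4e-09). Each of these 3 had an adjusted p of 0.365 with an estimated correlation, and none of the 9 held. Transporters (median 0.57, camera adjusted p = 0.00189), chlorophyll synthesis (0.12, 0.0125), C4 enzymes (0.33, 0.0212), leaf development and vein regulators (0.14, 0.0307) and starch and sucrose (0.13, 0.0307) were also called as higher, and photorespiration as lower (−0.60, 0.0420). Each of these 6 had an adjusted p of 0.655 or 0.706 with an estimated correlation. Without the mature F. brownii library these 3 alone of the 9 were still called, with medians of 0.65, 0.22 and 0.47. Without F. brownii the cyclic electron flow call ended as well (camera adjusted p = 0.280), and the C4 enzymes were called as lower (median −0.54, camera adjusted p = 0.0134). PPDK was then at −1.22 and PPC1, at 0.67 with all species, at −0.81, and neither passed with or without F. brownii. The C4 enzyme call also ended without F. kochiana (0.0555) or F. bidentis (0.0770).

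Setting the 6 C4 and C4-like species against the 5 C3 and C3-C4 species again gave higher C4 cycle transcripts. PPDK was higher by 5.70 ± 0.60, PPC1 by 4.58 ± 0.49, NADP-ME1 by 4.21 ± 0.50 and NHD1 by 4.34 ± 0.35. In limma 203 loci passed, 141 higher and 62 lower, and 171 with TMM. Of the C4 enzymes 18 of 24 were higher (19 adjusted over the list alone; camera adjusted p = 4.3e-43; adjusted p = 0.0019 with an estimated correlation), of the transporters 6 of 7 (7 adjusted over the list alone; camera adjusted p = 1.1e-17; adjusted p = 0.0087 with an estimated correlation) and of cyclic electron flow 15 of 20 (20 adjusted over the list alone; camera adjusted p = 2.9e-31; adjusted p = 0.0078 with an estimated correlation). PNSB2 and NDHN, subunits of the NDH complex, were higher by 2.06 and 1.84. With TMM the count was 5 in the transporters and 11 in cyclic electron flow.

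In photorespiration 4 of 24 were lower, and 16 lower and 2 higher adjusted over the list alone (camera adjusted p = 3.9e-11; adjusted p = 0.0788 with an estimated correlation). mLPD1 was at −1.59, GLDT, a subunit of glycine decarboxylase, at −1.46 and GS2 at −1.29. The Calvin-Benson cycle had 4 of 22 lower, and 5 lower and 1 higher adjusted over the list alone, RBCS1A (−2.25), RBCS1B (−1.77), RBCS2B (−1.47) and RCA (−1.59), with RCA at −1.59 and an adjusted p of 0.0691 under TMM (camera adjusted p = 0.0441; adjusted p = 0.649 with an estimated correlation). TMM scaling ended the list call (camera adjusted p = 0.0656), as did leaving out the mature F. brownii library (0.152). The 4 Rubisco small subunit loci correlated over the 18 libraries (Pearson r from 0.705 to 0.918). Counts of them may therefore count the same reads more than once. LHCB2.2 and LHCB1.3, antenna proteins of photosystem II, were at −1.13 and −1.26, and PSAD2 of photosystem I was at 1.19, and all 3 calls ended under TMM (adjusted p = 0.0538, 0.110 and 0.0781), with changes that moved by less than their SE. Camera called 5 other lists, of which none held with an estimated correlation. These were starch and sucrose, higher (adjusted p = 1.0e-05; adjusted p = 0.338 with an estimated correlation), heat shock, higher (adjusted p = 0.00517; adjusted p = 0.338 with an estimated correlation), photosystem I, higher (adjusted p = 0.00659; adjusted p = 0.649 with an estimated correlation), photosystem II, lower (adjusted p = 0.00813; adjusted p = 0.649 with an estimated correlation) and the epidermis markers, lower (adjusted p = 0.0476; adjusted p = 0.504 with an estimated correlation), the last not with TMM (adjusted p = 0.0694). Leaving out the mature F. brownii library ended the photosystem II call (camera adjusted p = 0.152). Leaving out a species ended the Calvin-Benson call (F. pringlei, F. sonorensis, F. brownii or F. kochiana; camera adjusted p from 0.152 to 0.284), the photosystem II call (the same 4 species; 0.0690 to 0.280), the photosystem I call (F. cronquistii, F. palmeri or F. trinervia; 0.0513 to 0.199) and that of the epidermis markers (F. cronquistii, F. pringlei, F. pubescens or F. sonorensis; 0.0540 to 0.140). BAM3, a starch-degrading amylase, was higher by 1.35, SCR by 2.29, and SWEET12 was at −1.46. Outside the lists AT1G76560 rose by 4.99 and AT1G49810 by 4.03, and AT4G14270 and AT3G63250 fell by 2.87 and 1.86.

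Summed over its loci, each of 4 C4 families was higher in the C4 and C4-like species. These exact permutation tests over 462 splits of the 11 species were chosen after seeing the data, and their p-values are adjusted over 8 families. Related species are not interchangeable, so these tests do not part photosynthetic type from shared ancestry. The sums were averaged over the stages that each species had, without centring for stage. F. palmeri, F. vaginata and F. sonorensis had juvenile leaves alone and F. kochiana mature leaves alone, so leaf age enters these comparisons. PEP carboxylase was 23.3-fold higher (adjusted p = 0.00693), NADP-malic enzyme 13.5-fold, and alanine aminotransferase 10.9-fold (each of the last pair adjusted p = 0.00577). Aspartate aminotransferase stood at 2058 ± 824.4 against 503.0 ± 226.8 RPM (adjusted p = 0.00577). The small subunit of Rubisco stood at 0.289 of the level in the other species (adjusted p = 0.00693) and glycolate oxidase at 0.539 (adjusted p = 0.0317). For glycolate oxidase the groups of species overlapped (1828 to 4881 against 3753 to 8460 RPM), and its locus GOX1 was higher in mature leaves above. The P protein of glycine decarboxylase at 0.586 (adjusted p = 0.0965) and carbonic anhydrase at 1.26-fold (adjusted p = 0.340) did not pass. With 1 value per species 6 loci passed, in juvenile libraries 36, in mature libraries 7, and with edgeR 637. Leaving out F. cronquistii, F. angustifolia, F. bidentis, F. vaginata, F. palmeri or F. brownii gave 83, 116, 120, 124, 128 or 413 loci.

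The stage difference was not shown to differ by type at any locus. For PPDK the stage difference of the C4 and C4-like species minus that of the others was −1.88 ± 0.37 on the log2 scale (adjusted p = 0.441). The expansins EXPA4 and EXPA8 were at 1.96 ± 0.55 and 1.92 ± 0.59 in this contrast (adjusted p = 0.632 and 0.648). In limma 0 loci passed, 1027 had an unadjusted p under 0.05, and leaving out F. brownii gave 1 locus. No tool other than limma was run on this contrast. TMM moved the median of all loci from 0.13 to 0.02. Camera called 7 lists, led by photosystem II (median −0.44, adjusted p = 1.2e-07; adjusted p = 0.583 with an estimated correlation), and none held. Photosystem I, the Calvin-Benson cycle (each camera adjusted p = 8.3e-05), C4 enzymes (0.00221) and photorespiration (0.0197) were also called in the lower direction, and primary cell wall (0.00890) and cytosolic ribosome genes (0.0107) in the higher. Without F. brownii the photosystem II median was −0.18 (camera adjusted p = 0.0405). Each of the other called lists lost its call when 1 species was left out, among them the C4 enzymes without F. pubescens (camera adjusted p = 0.588) and photosystem I without F. brownii (camera adjusted p = 0.0717). The photosystem II stage median was −0.60 in F. brownii, 0.44 in F. bidentis and 0.35 in F. trinervia, and 0.49 to 0.74 in the other 4 species.

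On average, leaf libraries resembled the other stage of their own species more than the other stage of other species. The Spearman correlation between the stages of a species averaged 0.842 ± 0.0624 (SD, n = 7 species), from 0.757 in F. brownii to 0.943 in F. bidentis. It exceeded that between different stages of different species by 0.0846 (one-sided exact permutation p = 0.000198, the smallest that the pairings of 7 species can give). This did not hold for every species. The juvenile library was closest to the mature library of its own species in 5 of 7 species, and in 4 with a filter of 10 RPM. F. brownii, at 0.757, lay at the mean between different stages of different species (0.758). The mean between different species at the same stage was 0.849, and its difference from the mean within species (−0.00665) was not tested. That difference was 0.00441, 0.00386 or 0.00485 without F. pringlei, F. angustifolia or F. brownii. After centring each stage, species of the same type were more alike than species of different types by 0.106 in Spearman correlation, which did not pass (one-sided permutation p = 0.0813, 100000 resamples). The permutation p-values that follow are one-sided as well. Leaving out F. brownii or F. sonorensis gave 0.160 (permutation p = 0.0290) and 0.159 (permutation p = 0.0333). Leaving out F. bidentis or F. trinervia gave 0.0373 (permutation p = 0.271) and 0.0440 (permutation p = 0.245).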

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

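The listed-loci test of ancestry, the test of totals without the abundant loci, and the splits for C3-C4 against C3, C4 against C4-like and the stage difference by type were chosen after their results were seen. In 34 groups of values 5 values stood far from the rest, where chance gives about 1 in 20, or 1.7. For none of the 23 lists did the stage median lie on 1 side of 0 in every C4 and C4-like species and on the opposite side in every other species. The mitochondrial share of reads of mature F. brownii was 0.640%, and the other mature libraries lay between 0.0494% and 0.241%. In F. pubescens the median stage difference on the log2 scale was 1.41 for C4 cycle enzymes (other species 0.21 to 0.58), 0.93 for the Calvin-Benson cycle (−0.09 to 0.18) and 0.78 for starch and sucrose (−0.52 to −0.03). In F. brownii it was −0.60 for photosystem II (0.35 to 0.74). No explanation was tested for these 5 values.

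For the loci that differed between the C4 and C4-like species and the others, library depth was weighed first. With every library thinned to the lowest total, 95.6% of the loci still passed, which argues against depth as the cause. Shared ancestry may account for part of the pattern, since by textbook knowledge every C4 or C4-like species here except F. brownii belongs to a single lineage, clade A. Among 387 other loci called without F. brownii, it lay nearer to clade A at 19.6% (exact 95% interval 15.8 to 24.0%, with loci taken as independent). Ancestry would give such a low share, but so could a C4-like type short of full C4, so these loci do not settle it. The share was 11.7 to 42.3% for the 5 C3 and C3-C4 species left out in turn, at fewer loci that were called with F. brownii among the C4-like species. Among 24 listed C4 loci F. brownii had a share of 41.7% (22.1 to 63.4%). On a scale from 0 at the C3 and C3-C4 species to 1 at clade A, its median position at listed loci was 0.479 (quartiles 0.392 to 0.551), against −0.170 to 0.254 in those 5 species, which goes against ancestry alone, but the quartiles of F. pubescens (0.0853 to 0.518; share 29.2%, against 0% in the other 4) overlap it, so ancestry and type cannot be told apart there and photosynthetic type stays open.

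More loci were lower than higher in mature leaves. A few abundant loci taking more of the reads could give such an excess, but the test left this open. With totals taken without the 50 most abundant loci, 35.3% of the 6742 loci that passed were higher, against 25.3% with all loci, so composition and leaf age cannot be told apart here. Leaf age itself stays open as a biological difference.

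Other splits of the samples were counted with a species correlation estimated from a subset of loci, which gives slightly different real counts for the types. For leaf age 1 of 100 drawn splits, the real one, gave as many as 7291 loci (highest other 5332, in a split that parts 5 of the 7 pairs). Of the 64 that part every pair 1 did, again the real one (highest other 2337). Both shares are under 0.05, so a chance split is an unlikely source of this count. For the C4 and C4-like species against the others 1 of 100 drawn splits, the real one, gave as many as 197 (highest other 146), also a share under 0.05. Related species are not interchangeable, so these splits do not part photosynthetic type from shared ancestry. With 10 splits each, a share under 0.05 cannot be reached for C4 against C3 (1 as large, real 182, highest other 32), C4-like against C3 (2, real 29, highest other 59), C3-C4 against C3 (10, real 0, highest other 5) and C4 against C4-like (10, real 0, highest other 3). For the stage difference by type all 35 splits reached the real count of 0 (highest other 16), which a count of 0 makes certain, so chance cannot be excluded.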

How the results depend on the processing

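The edgeR, limma-voom and thinning alternatives, and leaving out the mature F. brownii library or a species from the list tests, were chosen after seeing the data. No value of a named gene that passed as reported or under the setting changed direction, while 110 of 11646 values did where neither passed. Both counts hold repeats, since in some comparisons the fit without F. brownii enters under more than 1 setting. Leaf age passed 7291 loci and gave 4853 with a mean of at least 10 RPM, where fewer loci were tested, and 3840 without the species block (the pairing); other settings stayed within 1.5 times. C4 against C3 (184) gave 1 with 1 value per species, 12 in juvenile and 29 in mature libraries, 1123 with edgeR, 105 with limma-voom and 38 to 261 leaving out each species. C4-like against C3 (29) gave 46 with no filter, 0 with 1 value per species, 0 in juvenile libraries, 60 with edgeR, 19 with limma-voom, 79 without F. brownii and 3 to 79 leaving out each species. C3-C4 against C3 (0) gave 10 with no filter, 2 in mature libraries, 14 with edgeR and 0 to 19 leaving out each species. C4 against C4-like (0) gave 1 with no filter, 14 with edgeR and 0 to 5. The C4 and C4-like species against the others (203) gave 6 with 1 value per species, 36 in juvenile and 7 in mature libraries, 637 with edgeR, 413 without F. brownii and 83 to 413. The stage difference by type (0) gave 0 to 1, and 1 without the mature F. brownii library. Named genes that passed (212) numbered 136 to 215. Of 56 list calls by camera 9 held with an estimated correlation, and leaving out each species gave 49 to 60. Fry made 25 calls over the same lists, which were not matched to those of camera. Similarity by type (0.106) ran from 0.0373 to 0.160. Without F. cronquistii or F. pringlei 1 C3 species is left, assumed to vary like the other groups. Fewer libraries by construction enter the separate stages and left-out species; elsewhere the cause was not tested. Not run were mature libraries for the C4-like contrasts, with 1 C4-like species, and the out-group. Depth limits loci near the 0.328 to 0.556 RPM that a count of 0 allows.

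The log2 values of named genes that changed direction follow, and for left-out species the range over all of them. For C4 against C3 the changed values were SEP3 at −0.31 in juvenile libraries. Leaving out each species gave PCK1 −0.017 to 1.97, LHY −0.58 to 3.30 and SEP3 −0.29 to 0.59. For C4-like against C3 the changed values were CESA1 at −0.039 in juvenile libraries. Leaving out each species gave CA2 −0.092 to 0.77 and CA3 −0.26 to 2.41. For C3-C4 against C3 the changed values were CA4 at −0.0020 with quantile normalization, PPC1 at −0.022 in juvenile libraries, EXPA5 at −0.063, HSP17.6A at −0.17, PRR9 at 0.23 and PPC3 at 0.099 in mature libraries. Leaving out each species gave PCK1 −0.54 to 1.48, NDHL −0.23 to 1.78, RPL4D −1.80 to 0.38, GLN1;1 −1.69 to 0.48, HSP101 −0.034 to 1.45, PPC1 −0.023 to 0.057, CA1 −0.097 to 0.38, CA4 −0.12 to 0.35, AMK2 −0.16 to 0.71, RPS18A −0.16 to 1.303, ELF3 −0.86 to 0.27, CA2 −0.53 to 0.35, EXPA5 −0.28 to 1.19 and PRR9 −1.24 to 0.084. For C4 against C4-like the changed values were CA4 at 0.021 with TMM, NADP-ME1 at −0.11, AlaAT1 at −0.048, AlaAT2 at −0.091, CA1 at −0.22 and CA2 at −0.20 with quantile normalization, AlaAT2 at −0.020 with 1 value per species, XCP1 at 0.017, NADP-ME1 at −0.087 and CA4 at 0.040 in juvenile libraries, CA4 at 0.33 with edgeR, CA4 at 0.023 with limma-voom, PPC3 at −0.062, PPDK at −0.15, AlaAT2 at −0.059, CA1 at −0.21 and CA2 at −0.20 without the mature F. brownii library, CA1 at −0.013 without F. brownii. Leaving out each species gave AMK2 −0.35 to 2.83, NHD1 −0.016 to 1.32, PPC1 −0.81 to 1.29, PPC2 −0.86 to 1.44, PPC3 −0.94 to 1.06, PPDK −1.22 to 0.97, NADP-ME1 −0.49 to 0.56, NADP-ME3 −0.69 to 0.96, NADP-ME4 −0.56 to 0.95, ASP5 −0.35 to 0.99, AlaAT1 −0.67 to 0.58, AlaAT2 −0.82 to 0.58, CA1 −0.18 to 0.60, CA2 −0.30 to 0.54, CA4 −0.57 to 0.28, PRR5 −1.12 to 0.31 and CA3 −0.44 to 1.78. For the C4 and C4-like species against the others the changed values were SEP3 at −0.16 in juvenile libraries, SEN1 at −0.054, CA1 at −0.17, CA2 at −0.14 and CA4 at −0.13 in mature libraries, ASP1 at −0.014 without the mature F. brownii library. Leaving out each species gave SEP3 −0.11 to 0.35 and ASP1 −0.086 to 0.23. For the stage difference by type the changed values were PCK1 at −0.18 and AOS at −0.40 without the mature F. brownii library. Leaving out each species gave PCK1 −0.18 to 0.70, AOS −0.40 to 0.97, NAD-ME1 −0.32 to 0.054 and JAZ1 −0.21 to 0.76. The cause was not tested.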

Other observations

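The test of the difference between photosystem lists was chosen after its result was seen. A hypothesis drawn from these data is that the balance of photosystem I over photosystem II transcripts may be higher in C4 and C4-like leaves. The mean log2 level of 16 photosystem I loci minus that of 24 photosystem II loci, centred within stage, was 0.30 ± 0.23 (SD, n = 6 species) in the C4 and C4-like and −0.28 ± 0.23 (n = 5) in the other species. The difference was 0.58 (two-sided exact permutation p = 0.00649 over 462 splits). F. brownii, the C4-like species outside clade A, stood at −0.15, within the −0.66 to −0.055 of the C3 and C3-C4 species. The 5 clade A species stood at 0.27 to 0.49, so the difference rested mainly on them. Shared ancestry therefore stays open beside photosynthetic type.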
